A study of Drosophila melanogaster with 3 samples.

How the data were processed

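Anti-GFP chromatin immunoprecipitation followed by sequencing was done on whole embryos of a nau-eGFP line in 3 biological replicates, per the labels and the sample descriptions. The antibody label names nau, whereas the description names anti-GFP, and the description was followed. The age label holds no plausible range of hours, so the 4 to 24 h of the source name was used. The labels give sonication and a fragment range of 200 to 800 bp. The authors deposited region lists in the narrowPeak format on the builds dm6 and dm3. These were 1 list per replicate and 1 list from the pooled replicates, each of 30000 regions made as input for IDR, and an IDR-thresholded list of 3767 regions on dm6 and 4987 on dm3. A control file per build was used for the lists, per the deposited read-me files. The aligner, the peak caller and the IDR threshold are not given in the sources used here. The signal value of each region is the authors' deposited measure of enrichment, on a scale the sources do not name. The deposited -log10 q value in the same lists entered no test. The distance of the summit from the start of the region was taken as the authors deposited it.

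Every list was sorted by signal value. The IDR list was identical to the 3767 strongest regions of the pooled dm6 list, so signal rank and IDR rank were the same. Replicate lists have the same length of 30000, a fixed number set before thresholding, so their lengths carry no information on depth. The number of reads per replicate was not used here, and intervals cover counting error only. In the IDR list, 28 entries repeated the interval of another entry with a further summit, and these were kept as separate summits.

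Positions are on dm6 (Release 6 of the Drosophila genome), 1-based. Genes were the 13945 protein-coding genes of Ensembl release 115 (BDGP6.54) on 6 chromosome arms. Because an annotation of dm3 was not used here, locations, motifs and genes were analysed on dm6 alone, and no coordinates were converted. Summits were classed in the order promoter (500 bp either side of a TSS), 5′ UTR, 3′ UTR, coding exon, other exon, intron and intergenic, and compared with 1000 random placements outside unsequenced bases. Motif words were searched on both strands within 100 bp of the summit and in 6946 flanking windows 1000 bp to either side with no IDR summit within 300 bp. Fisher's exact tests were 2-sided with Benjamini-Hochberg adjustment, over 10 E-boxes and over 13 other words. For gene lists, a gene counted when an IDR summit lay in its body or up to 2 kb upstream, and lists were compared with 100000 random lists matched in 20 bins of length, adjusted over 16 lists. All 353 list genes were matched to the annotation, 13 list names through older or alternative symbols. Rank relations used Spearman's rho with 100000 permutations, and a partial rho with the GC share of the window held constant with 10000.

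The named genes were chosen by a rule set before the data were examined. They were nau, the genes assigned to the 20 strongest IDR regions, up to 4 members of each list with the strongest summit, and up to 4 members of the muscle lists without a summit, in list order. The result of 1 gene that this rule names is not reported here. Values per replicate were taken from its own 3767 strongest regions and are given as mean ± SD (n = 3). Genes and regions are not biological replicates. The tests, lists and most alternatives were fixed before the data were examined. Comparisons against flanks outside coding exons, the lists of other ubiquitous genes, with and without genes named as duplicates of another member (such as Prosalpha3T), the combined lists, the scan of all hexamers and the matching on neighbouring TSSs were chosen after the data were seen. The alternatives covered window widths, backgrounds, promoter widths, gene assignment, the stronger part of the IDR list, the number and overlap of regions compared, the build, and leaving out each replicate, where IDR regions had to match the strongest of both other replicates.

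The tests were tried on simulated data. With CAGCTG planted in 10% of 3767 random windows, the E-box test passed in 100% of 20 runs, and without planting it passed in 2 of 20. For the gene lists, simulated over 13945 genes, 99.4% of tests passed when a summit was placed in 75% of a list, and 1.25% of 160 passed without. In these simulations a test passed at p under 0.05 before adjustment. Smaller planted shares were not simulated, so the chance of finding a weaker excess in a list is unknown. Computation used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.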

Results

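Chromatin bound by the product of nautilus (nau), a basic helix-loop-helix (bHLH) transcription factor of the MyoD family, was mapped in whole Drosophila melanogaster embryos. The embryos came from a transgenic line carrying nau with a C-terminal GFP, were of both sexes and were collected between 4 and 24 h. Chromatin was sonicated to fragments of 200 to 800 bp and precipitated with an antibody to GFP. The series holds 1 group with 3 biological replicates, so the comparisons are between places in the genome and not between conditions. For each replicate the authors gave a list of 30000 candidate regions with a signal value, and they gave 1 list from the pooled replicates and 1 list thresholded by the irreproducible discovery rate (IDR). Signal values are the authors' own and serve here to rank and filter regions within a list. Read depth is unknown from the sources used here, and confidence intervals cover counting error only.

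The IDR list on the dm6 build held 3767 regions, of which 874 lay on chromosome arm 3L, 861 on 3R, 736 on 2L, 673 on 2R, 605 on X and 18 on chromosome 4. Per megabase this was 31.3 regions on 2L, 31.1 on 3L, 26.8 on 3R, 26.6 on 2R, 25.7 on X and 13.4 on chromosome 4. The strongest region, with a signal value of 2783, lay in an intron of CG11050 at 2L, 6612430 to 6612939. The next lay at the promoters of Ugalt and eIF2Bbeta (X, 2703664 to 2704086, signal value 2732), a UDP-galactose transporter and a translation initiation factor subunit. The region ranked 3 was in an intron of u-shaped (ush), a cofactor of GATA factors, and upstream of cabut (cbt), at 2L, 480566 to 481368. These regions held mean ranks of 1.67 ± 0.577, 1.67 ± 1.15 and 2.67 ± 0.577 in the replicates' own lists (SD, n = 3).

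Other genes at the 20 strongest regions were plexus (px), jp, brwl, PNPase, Gprk2, Trl, CG42507, sbb, CG31145, Tina-1, Chro, Ssl1, mRpS23, CenG1A, Gapdh2, CG32772, CG18549, HmgZ and HmgD. Trl encodes the GAGA factor and Chro a chromatin protein of interbands. Gapdh2 encodes a glycolytic enzyme, and its promoter region lay at X, 15867745 to 15868215 with a mean rank of 19.7 ± 10.7 (SD, n = 3). The intergenic regions among the 20 that fell in no gene's window had CG4004, hll, CG13323 and tara as the genes with the nearest transcription start site (TSS). For the region at PNPase and Gprk2 (3R, 31404479 to 31404872), ranked 10 and 12 in replicates 1 and 2, replicate 3 listed no summit within 100 bp. None of these 20 regions named muscle genes of the fixed lists, and ush was the only member of the lists fixed before the data were examined, in that of fat body and hemocyte genes.

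The replicates ranked many of the same places highest. Of the 3767 strongest regions of a replicate, 63.3% ± 1.88 (SD over 3 pairs) had a summit within 100 bp of a summit among the 3767 strongest of another. The pairs gave 61.7% for replicates 1 and 2, 65.4% for 1 and 3, and 62.9% for 2 and 3. Random placements of 1 list gave 0.585% on average and at most 0.982% in 100 placements. Of the IDR regions, 1940 (51.5%) were matched among the strongest of all 3 replicates, and 86 (2.28%) in none of them. The count of IDR regions on the older build dm3 was 4987, which is 1.32 times the dm6 count. The dm3 list reaches down to a signal value of 136 and the dm6 list to 166, and 3645 regions of the dm3 pooled list reached the latter value.

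Promoters and introns held most summits, while coding sequence held almost none. Within 500 bp of the TSS of a protein-coding gene lay 38.1% of IDR summits (95% Wilson interval 36.6 to 39.7), and the 3767 strongest regions of each replicate gave 40.4% ± 0.801 (SD, n = 3). Random placements on the same chromosomes gave 11.5%, a ratio of 3.32 (2-sided permutation p = 0.002, the smallest that 1000 placements can give). Introns held 42.7% of summits against 39.2% of random placements, and intergenic sequence 17.4% against 30.1%. Coding exons held 8 of the 3767 summits, 0.212% against 13.3% of random placements, and 3′ UTRs held 0.876% against 5.11%. The 5000 lowest-ranked regions of the pooled list also lay below random placements, at 1.9% in coding exons and 3.02% in 3′ UTRs. Part of this shortfall was thus shared by weak regions. The classes were assigned in a fixed order with promoters first, so exons near a TSS count as promoter.

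**Figure D1:**
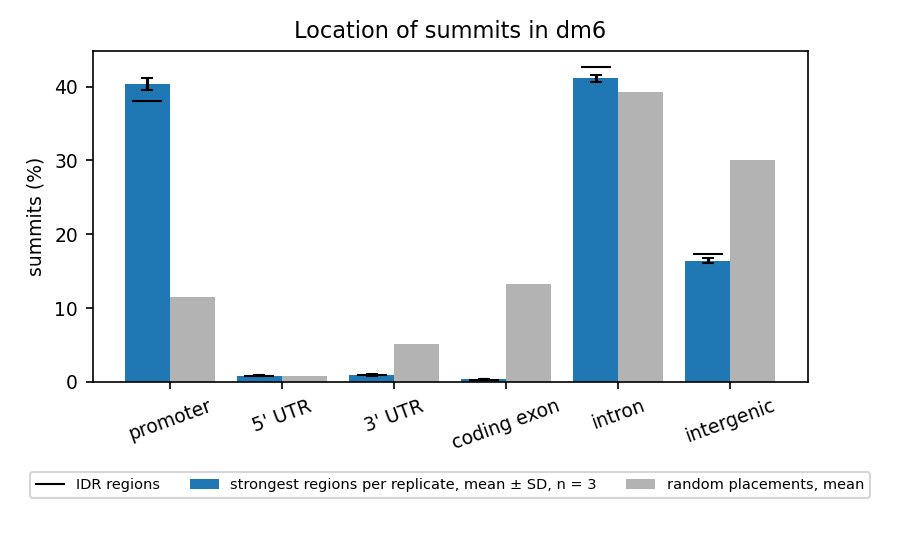
Share of summits (percent) in each annotation class on dm6. Blue bars are the 3767 strongest regions of each replicate (mean ± SD, n = 3), black dashes the IDR regions and grey bars the mean of random placements. Promoters hold 38.1% of IDR summits and 11.5% of random placements, and coding exons 0.212% and 13.3%; other exons held 0 IDR summits and are not drawn.

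Dimers of bHLH factors bind the E-box CANNTG, and CAGCTG, a form bound by MyoD, was the main word of this test. CAGCTG was present within 100 bp of 570 of 3767 IDR summits, or 15.1% (95% Wilson interval 14.02 to 16.3). Flanking windows 1000 bp away held it in 8.59%, a ratio of 1.76 (2-sided Fisher's exact test, Benjamini-Hochberg adjusted over 10 E-boxes, p = 2.87e-23). In the replicates' own strongest regions the share was 14.9% ± 0.107 and the ratio 1.70 ± 0.0885 (SD, n = 3), above 1 in 3 of 3 replicates. Along the sequence, CAGCTG occurred 1.19 times per kb within 20 bp of the summit and 0.474 times per kb beyond 400 bp. This rise was not particular to CAGCTG, as the forkhead word RTAAAYA gave 3.89 and 1.97 per kb at the same distances. Regions are not biological replicates, so these p-values describe places in the genome.

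**Figure D2:**
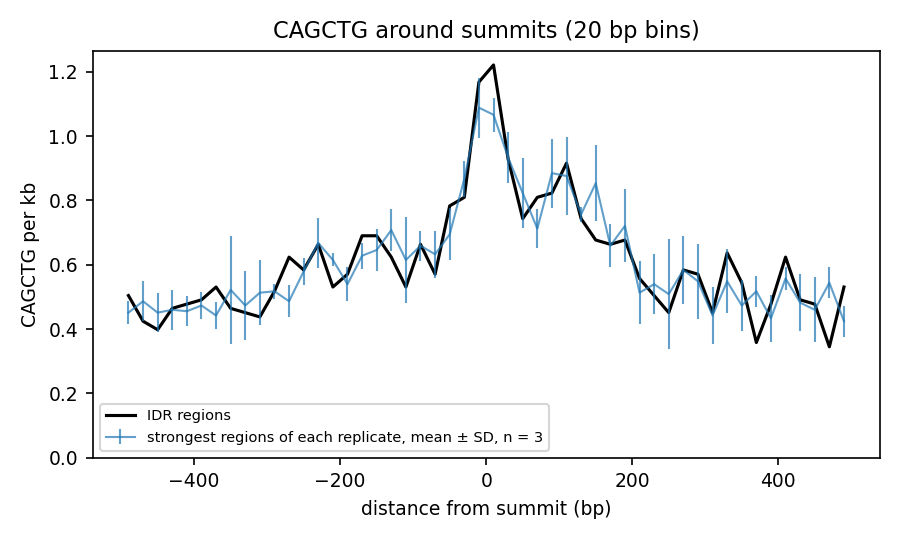
Occurrences of CAGCTG per kb (y axis) by distance from the summit in bp (x axis), in bins of 20 bp. The black line is the IDR list and the blue line the 3767 strongest regions of each replicate (mean ± SD, n = 3). The IDR line averages 1.19 per kb within 20 bp of the summit and 0.474 per kb beyond 400 bp.

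Of the other 9 E-boxes, CAGATG was less frequent at summits than in flanks, 6.56% against 8.44%, a ratio of 0.777 (adjusted exact p = 0.00252). It was below 1 in all 3 replicates, at 0.789 ± 0.0823 (SD, n = 3). CATATG gave 8.28% against 7.18% (adjusted exact p = 0.142), CACGTG 2.57% against 2.59% (adjusted exact p = 1) and CACCTG 6.53% against 7.24% (adjusted exact p = 0.296). Flanks lay in coding exons in 14.5% of cases. With those flanks left out, a choice made after the data were seen, the CAGCTG ratio was 1.95 and CAGATG no longer passed, with a ratio of 0.845 (adjusted exact p = 0.0919). CAAATG, at 0.960 against all flanks (adjusted exact p = 0.455), then passed as less frequent, with a ratio of 0.890 (adjusted exact p = 0.0185).

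Among 13 binding words of other factors, 5 were more frequent at summits than in flanks and 1 was less frequent. The forkhead (Fox) word RTAAAYA was present at 40.2% of summits against 28.1% of flanks (ratio 1.43, adjusted exact p = 3.12e-36). The GAGA word was present at 6.37% against 3.86% (ratio 1.65, adjusted exact p = 6.28e-08), and its ratio was 3.31 against windows matched in GC, which held it in 1.92%. Against flanks outside coding exons the ratio was 1.47 for GAGA and 1.28 for Fox, and Fox gave 1.38 against windows matched in GC. The promoter words DRE and Ohler1, the latter bound by M1BP, gave 1.59% against 0.648% (adjusted exact p = 1.93e-05) and 0.823% against 0.288% (adjusted exact p = 0.000637). The word of Mef2, a muscle differentiation factor, gave 9.50% against 7.69% (adjusted exact p = 0.00329). The word of the TEAD factor Scalloped was less frequent, 3.77% against 4.79% (adjusted exact p = 0.0302). Per replicate the ratios were 1.45 ± 0.0443 for Fox, 1.79 ± 0.133 for GAGA and 1.33 ± 0.141 for Mef2 (SD, n = 3), all above 1 in 3 of 3 replicates. The Mef2 call ended against windows matched in GC (ratio 1.14, adjusted exact p = 0.0685) and against flanks outside coding exons (ratio 1.09, adjusted exact p = 0.347). The calls of Scalloped and Ohler1 ended without replicate 1, which left 2287 regions: the ratio went from 0.786 to 0.803 for Scalloped (adjusted exact p = 0.148) and from 2.86 to 2.44 for Ohler1 (adjusted exact p = 0.0587). GATA did not pass against flanks (ratio 1.08, adjusted exact p = 0.316) or flanks outside coding exons (ratio 0.997, adjusted exact p = 0.969) but passed against windows matched in GC (ratio 1.32, adjusted exact p = 0.000359) and against the 5000 lowest-ranked regions of the pooled list (ratio 1.34, adjusted exact p = 0.000575). Against those 5000 regions Zelda (ratio 1.77, adjusted exact p = 0.0239) and Su(H) (ratio 0.697, adjusted exact p = 0.0278) passed too, while against flanks they gave 1.14 and 0.812 (adjusted exact p = 0.493 and 0.267).

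The strongest regions held CAGCTG less often than the rest of the IDR list. With the list divided into 10 bins by signal value, 37 of the 377 strongest regions had it within 100 bp of the summit, 9.81% (95% Wilson interval 7.20 to 13.2), and in the next bin 11.9%. The other bins ranged from 14.4% to 17.8%. Across regions, Spearman's rho between signal value and CAGCTG was -0.0351 (2-sided permutation p = 0.0310, n = 3767 regions, which are not independent replicates). The relation did not pass within 50 bp (rho -0.0288, p = 0.0746) or at summits over 500 bp from a TSS (rho -0.00577, p = 0.782), and its sign changed within 250 bp (rho 0.0249, p = 0.128). With the GC share of the window held constant rho was -0.000287 (permutation p = 0.986). In the replicates' own strongest regions rho was -0.0332 (p = 0.0408), -0.0187 (p = 0.250) and -0.0377 (p = 0.0209), so that replicate 2 did not pass.

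**Figure D3:**
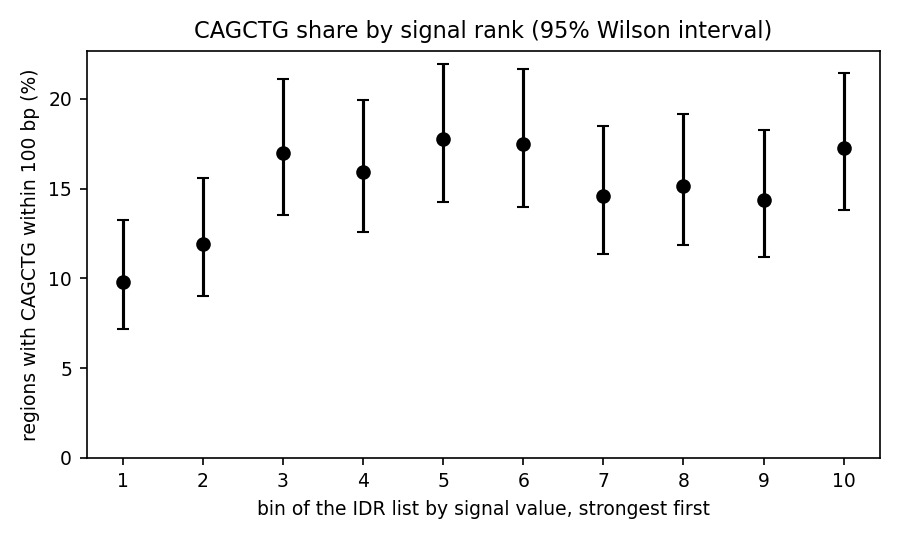
Share of IDR regions with CAGCTG within 100 bp of the summit (percent, y axis) in 10 bins of the list by signal value, strongest first (x axis). Points are shares and bars 95% Wilson intervals. The strongest bin lies at 9.81% and the others between 11.9% and 17.8%.

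A summit in the gene body or up to 2 kb upstream was found for 2497 of 13945 protein-coding genes. Of 16 gene lists fixed before the data were examined, 1 held more such genes than lists matched in gene length. Cytosolic ribosomal protein genes had a summit in 57 of 85 cases, where matched lists gave 8.79 on average with a 95% range of 4 to 15 (2-sided permutation test with 100000 lists, p = 2e-05, the smallest it can give, adjusted permutation p = 0.00032). The replicates gave 58.7 ± 1.15 genes (SD, n = 3). Among their strongest summits were those at the promoters of RpL7 (2L, 10200859 to 10201264, rank 59), RpS27 (3R, 25247299 to 25247690, rank 66) and RpLP0 (3L, 22075890 to 22076244, rank 122). Counting only summits over 500 bp from any TSS left 1 of the 85 genes. Proteasome genes had a summit in 1 of 25 cases, that of Prosbeta6, where matched lists gave 2.29 (adjusted permutation p = 1), and in 0 without replicate 1 or without replicate 2. That list holds 11 genes named as duplicates of another subunit, none with a summit, and without them, a choice made after the data were seen, it gave 1 of 14 against 1.246 (adjusted permutation p = 1).

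The muscle lists did not pass the test. Muscle identity factors had a summit in 8 of 22 cases against 8.10 in matched lists (adjusted permutation p = 1), and 5 against 5.96 without replicate 3. They included org-1 (promoter, X, 8455298 to 8455548, rank 514), nau itself (rank 684), Ptx1 (intron, 3R, 30921667 to 30921888, rank 729) and Poxm (promoter, 3R, 8334113 to 8334275, rank 843), while slou, Kr, vg and sd had none. Myoblast fusion genes gave 6 of 17 against 6.05 (adjusted permutation p = 1). Among them kirre, an adhesion receptor of founder cells, held 13 summits in a long gene (X, 2740384 to 3134532). Such counts are not adjusted for gene length. In the same list siz, mbc and rols held 3, 2 and 5, while sns, hbs, Ced-12 and blow had none. Sarcomere and contraction genes gave 10 of 31 against 9.98 (adjusted permutation p = 1), and 5 against 7.49 without replicate 3. Msp300, a giant nesprin-family protein (intron, 2L, 5149908 to 5150340, rank 97), CAP, TpnC73F and wupA led the list. The myosin heavy chain gene Mhc and the actin genes Act57B, Act87E and Act79B had no summit.

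Early mesoderm factors had a summit in 8 of 17 cases against 5.05 in matched lists (permutation p = 0.151 before adjustment and 0.67 after it). In the stronger 1883 regions it was 7 against 3.33 (permutation p = 0.0459 before adjustment and 0.245 after it). Without replicate 2 it was 7 against 3.93 (permutation p = 0.112 before adjustment). Mef2 held 9 summits, of which the strongest lay upstream of Mef2 and 142 bp from the TSS of Pdrg1 (2R, 9959710 to 9960124, rank 30). The others leading this list were biniou (bin, upstream, 3L, 6989084 to 6989324, rank 213), zfh1 (intron, 3R, 30767555 to 30767888, rank 269) and tinman (tin, promoter, 3R, 21378642 to 21378884, rank 516), while sna, bap, Him and Doc1 had none. Muscle attachment genes gave 13 of 20 against 7.94 (permutation p = 0.0268 before adjustment and 0.214 after it), and 12 ± 1 in the replicates (SD, n = 3). By nearest TSS it was 13 against 7.17 (permutation p = 0.00954 before adjustment and 0.0763 after it). Counting only summits over 500 bp from any TSS it was 10 against 5.49 (permutation p = 0.0341 before adjustment and 0.546 after it). Without replicate 3 it was 8 against 5.91 (permutation p = 0.407 before adjustment), and in the stronger 1883 regions 6 against 5.28 (permutation p = 0.880 before adjustment). They included Pax, encoding paxillin (233 bp from the TSS of Alp12, 2L, 19423533 to 19424088, rank 63), rhea, encoding talin (intron, 3L, 8547109 to 8547523, rank 392), stck and Fit1, while Tsp, Ilk, parvin and Lrt had none. Neuromuscular junction genes gave 8 of 16 against 6.90 (adjusted permutation p = 1), and 5 against 5.43 without replicate 3, led by the adhesion proteins caps, Fas3, Fas2 and trn, while the glutamate receptor genes GluRIIA, GluRIIB, GluRIIC and GluRIID had none. Without matching for length, early mesoderm, attachment and junction genes passed as well (Fisher's exact test, adjusted p = 0.0218, 3.33e-05 and 0.0183), and long genes collect more summits.

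No list of another cell type passed either. Notch pathway genes had a summit in 7 of 20 cases against 4.44 in matched lists (adjusted permutation p = 0.67), with mam, E(spl)m3-HLH, numb and neur leading. In the stronger 1883 regions it was 7 against 2.85 (permutation p = 0.0178 before adjustment and 0.143 after it). By nearest TSS it was 8 against 4.00 (permutation p = 0.0335 before adjustment and 0.179 after it). Without replicate 1 it was 6 against 3.28 (permutation p = 0.144 before adjustment), and with distal summits 4 against 2.71 (permutation p = 0.529 before adjustment). The bHLH partner and inhibitor genes gave 3 of 12 against 1.81 (adjusted permutation p = 1), namely hry, emc and da, the last encoding the E-protein partner of bHLH factors, and 1 against 1.26 without replicate 3. Neural genes gave 4 of 19 against 6.26 (adjusted permutation p = 0.911), among them elav (promoter, X, 523262 to 523724, rank 72), ChAT, pros and Syx1A, and 2 against 4.65 without replicate 3. Gut and endoderm genes gave 5 of 14 against 4.01 (adjusted permutation p = 1), led by fkh (promoter, 3R, 28585160 to 28585696, rank 51), Hnf4, dpp and cad. Epidermis and cuticle genes gave 4 of 15 against 4.97 (adjusted permutation p = 1), namely grh, ovo, mwh and wgn, but 2 against 3.75 without replicate 1, 2 against 3.71 without replicate 3 and 0 against 3.39 counting summits within 1 kb of a TSS. Trachea genes gave 3 of 12 against 4.87 (adjusted permutation p = 0.911), namely trh, bnl and tkv, and germline genes 3 of 12 against 2.78 (adjusted permutation p = 1), namely exu, vas and stai, but 1 against 2.42 by nearest TSS, 1 against 2.03 within 1 kb of a TSS and 0 against 1.72 in the stronger 1883 regions. Fat body and hemocyte genes gave 2 of 16 against 4.60 (adjusted permutation p = 0.67), namely ush and Pxn, and 1 under each of those 3 alternatives. Within 1 kb of a TSS the counts of other lists also fell, and so did those of their matched lists. The counts were 4 against 5.51 for muscle identity, 3 against 4.04 for fusion and 7 against 5.30 for attachment genes. For junction, neural and gut genes the counts were 5 against 4.47, 2 against 4.27 and 2 against 2.81. The strongest summits of kirre, Fit1, da, mwh, Pxn, vas, stai and Prosbeta6 lay at promoters, nearest to the TSS of Syx4, CG14995, Cdk1, CG9119, MEP-1, vig, CG9175 and CG4101 in that order.

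**Figure D4:**
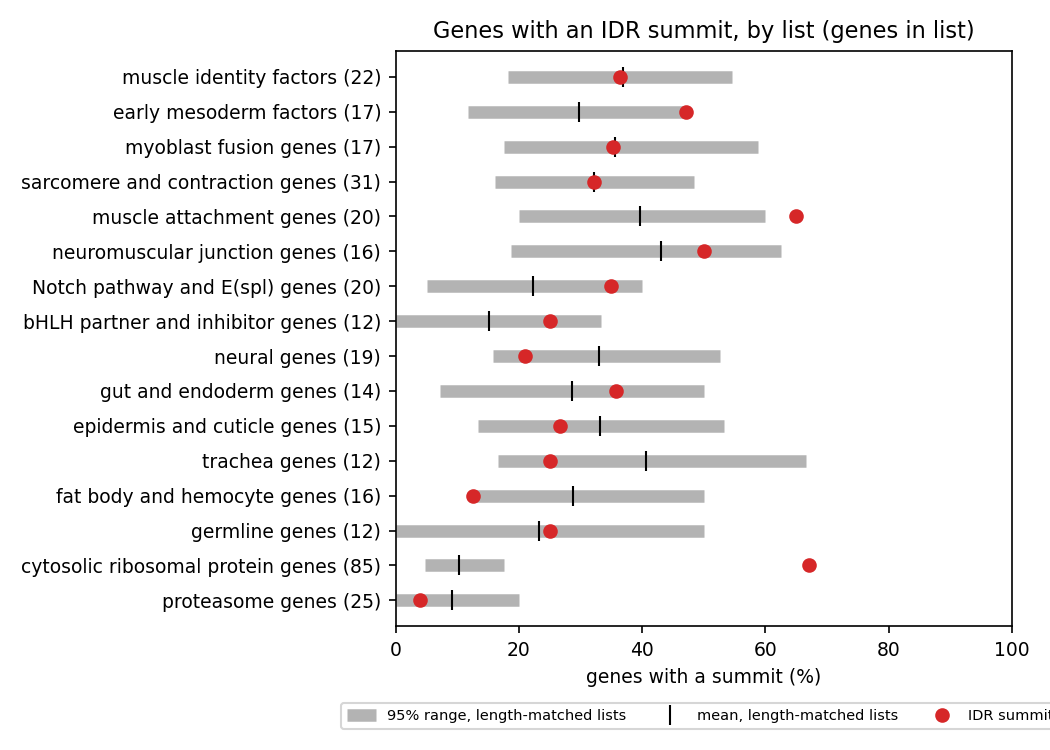
Share of genes with an IDR summit in the gene body or up to 2 kb upstream (percent, x axis) for each fixed list, with the number of genes in brackets. Red points are the observed shares, black ticks the mean and grey bars the 95% range of length-matched random lists. Cytosolic ribosomal protein genes lie at 67.1% against a range of 4.71% to 17.6%; muscle attachment genes, at 65%, lie above their range of 20% to 60% but did not pass after adjustment.

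The tagged gene nau (FBgn0002922, 3R, 23712814 to 23718357, minus strand) had 7 IDR summits in or within 10 kb of it. The region inside nau lay in an intron (3R, 23714013 to 23714178, signal value 419) with ranks of 597, 994 and 774 in replicates 1, 2 and 3. The strongest of the 7, at 3R, 23722826 to 23723075 (signal value 432, IDR rank 652), lay at the promoter of CG10365, as did 2 others, and 2 more were in introns there. The remaining region lay at the promoter of CG10301 (3R, 23709714 to 23709828, rank 773). The replicates' strongest regions gave 7.33 ± 1.53 summits in this stretch (SD, n = 3). Of 11995 genes with stretches of similar length, 34 (0.283%) had as many IDR summits. None of the 7 summits had CAGCTG within 100 bp. A tagged transgene adds copies of its own locus, and its extent was not given in the sources used here.

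**Figure D5:**
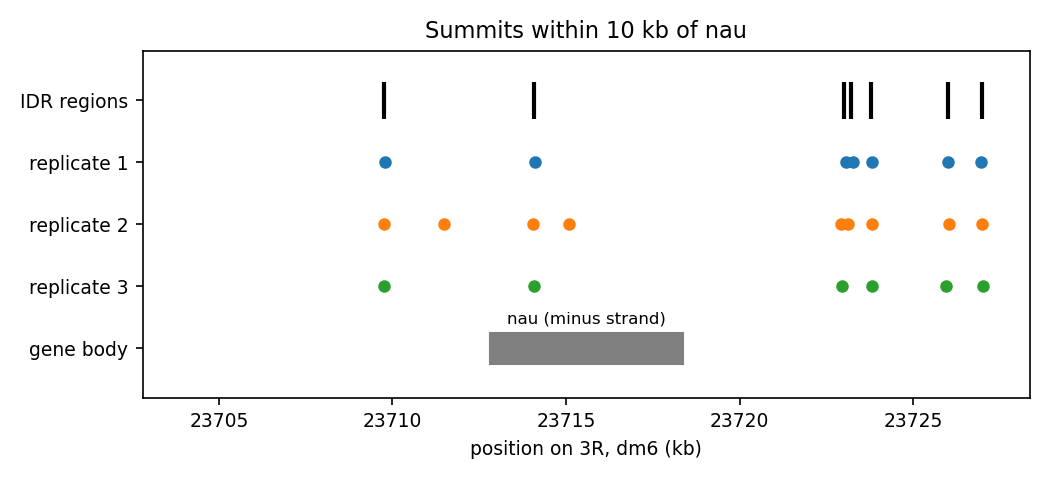
Summits within 10 kb of nau on 3R (x axis, position in kb, dm6). Black lines are the 7 IDR summits, coloured points the summits among the 3767 strongest regions of each replicate and the grey bar the body of nau. The 3 replicates mark a mean of 7.33 summits.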

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

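Of the tests here, those on ubiquitous genes, on CAGCTG by rank within promoter summits or with GC held constant in each class, and on the density around nau were chosen after the results were seen. The dm3 pooled list held 79 regions outside the 6 main chromosome arms, on heterochromatic and unplaced sequence that no location, motif or gene comparison used. This lies above the 3 regions that a count of 0 allows. Of these, 20 lay on 2RHet, 21 on 3LHet, 14 on 3RHet and 12 on XHet, and 3 regions of unplaced sequence (Uextra) were in the dm3 IDR list and so in its count of 4987. The dm6 lists held 0 regions outside the arms.

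Ribosomal protein genes stood far above length-matched lists, with a summit at 57 of 85. Summits of neighbouring genes falling in the windows of short genes do not account for it, since 56 of the 85 had a summit within 250 bp of their own TSS, where matched lists gave 4.64 (range 1 to 9). Marking of genes taken from their function, not from measurement, as used in every cell falls short of it for such genes as a combined set. Translation factor, ATP synthase, glycolysis, mitochondrial ribosomal protein and proteasome genes had a summit in 25.3% of 150 cases (exact 95% interval 18.6 to 33.1). This left out 25 genes named as duplicates that held no summit. That share lay below the interval of 56.0 to 76.9 for ribosomal protein genes, although above its own matched lists (12.2%). Of the single lists, glycolysis genes gave 5 of 11, or 45.5%, with an exact interval of 16.7 to 76.6 that reaches the ribosomal one. The intervals of translation factor, ATP synthase and mitochondrial ribosomal protein genes ended below it, at 43.8, 48.1 and 30.1. CAGCTG does not account for the excess at ribosomal protein genes either, being present at 6.45% of 62 ribosomal protein promoter summits against 16.6% of other promoter summits (2-sided Fisher's exact test, p = 0.0333). Signal common to many immunoprecipitations at strongly transcribed promoters was not tested, since no other immunoprecipitation was used here, and no biological explanation was tested because the series has 1 group.

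CAGCTG was rarer at the strongest regions. The mix of promoters and distal regions does not account for it, since the relation held within promoter summits (rho -0.0798, permutation p = 0.00268), where a mix leaves none; among distal summits, the class chosen before the test, rho was -0.00577 (p = 0.782). Base composition may contribute: windows of the strongest of 10 bins held 36.4% GC against 40.3% in the weakest bin, and with GC held constant rho was -0.000287 (permutation p = 0.986), and -0.0295 within promoter summits (p = 0.262) and 0.00908 within distal ones (p = 0.667). At constant GC, then, no relation passed in the whole list or in either class. The value for the whole list fell just short of the bound of 0 or above set before the test. It did not lie below 0 by more than chance either, so neither prediction was met and the explanation is not settled. No biological explanation was tested.

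The 7 summits around nau may reflect extra copies of the tagged locus. The stretch held 22 regions of the pooled list, against a median of 3 in stretches of similar length, and 75 of 11995 such stretches held as many. The densest other stretch of the same length within 100 kb, at 3R, 23652814 to 23678357, held 23. Because the extent of the transgene was not given, that stretch could lie on added copies too. The comparison thus cannot decide whether density sets the tagged locus apart, nor does it exclude added copies. The explanation cannot be told apart from a dense stretch of the genome without an untagged line. No biological explanation was tested.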

How the results depend on the processing

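Alternatives chosen after the data were seen were the regions ranked just below the IDR list, flanks outside coding exons, matching on neighbouring TSSs, single replicates' lists, the stronger part of the list and left-out replicates at nau, and left-out replicates for the 13 words. The share of strongest regions common to replicates (63.3%) became 72.3% with 1 bp of overlap, 71.6% with summits within 250 bp, 77.3% for the 500 strongest and 61.0% for the 5000 strongest, and 61.7% to 65.4% with each replicate left out. The rank relation of CAGCTG (rho -0.0351) became -0.0288 within 50 bp, -0.00577 at distal summits and 0.0249 within 250 bp. Leaving out each replicate gave -0.0651 to -0.0462. The number of gene lists that passed (1) became 0 with distal summits and 4 without length matching. With distal summits ribosomal protein genes fell to 1 of 85, which follows from leaving out promoters. The cause of the other changes was not tested.

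Promoter share, CAGCTG enrichment and the nau count kept their direction and, where tested, their side of the threshold in all alternatives run. CAGCTG ratios ranged from 1.44 within 250 bp to 2.41 against GC-matched windows. The promoter share itself was 28.0% with 250 bp and 47.8% with 1000 bp. The count of the 13 words that passed (6) became 9 against low-ranked regions, 5 against flanks outside coding exons and 4 without replicate 1. Over all results that answer a comparison, 46 of 56 alternatives kept direction and side of the threshold, stayed within 1.5 times for a count, or moved by less than the replicates' SD. Among single lists and words, 7 of 270 reversed. Apart from the ribosomal list, these were words that had not passed against flanks: Hox (0.969 against GC-matched windows, 0.995 against low-ranked regions, 0.940 against flanks outside coding exons), Tinman (0.988 against low-ranked regions), GATA (0.997 against flanks outside coding exons) and Su(H) (0.897 to 1.06 with a replicate left out). The nau locus on dm3 was not run, as an annotation of that build was not used here, and the IDR count has no version without a replicate. Unknown read depth leaves open how many weaker regions the lists miss.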

Other observations

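All tests in this part were chosen after the data were seen, except the comparison of CAGCTG with GC-matched windows. The gene with the most summits was bun, with 15, followed by RapGAP1, Svil and sbb with 14 each, CHES-1-like and kirre with 13 each, and Eip75B, Raf, Tlk, shn and ush with 12 each. Of all protein-coding genes, 124 had at least 5. These counts are not adjusted for gene length.

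Translation factor, ATP synthase, glycolysis, mitochondrial ribosomal protein and proteasome genes had a summit more often than length-matched lists as a combined set, 38 of 175 against 21.0 (2-sided permutation test, adjusted p = 0.00130 over 10 added lists). Without 25 genes named as duplicates of another member it was 38 of 150 against 18.3 (adjusted permutation p = 0.0002, from the smallest p that 100000 lists can give). Mitochondrial ribosomal protein genes gave 14 of 73 against 6.73 (adjusted permutation p = 0.0395), translation factor genes 15 of 51 against 8.47 (adjusted permutation p = 0.0609), glycolysis genes 5 of 11 against 1.95 (adjusted permutation p = 0.115) and ATP synthase genes 3 of 15 against 1.57 (adjusted permutation p = 0.447). The muscle lists of identity, fusion, sarcomere and attachment genes combined gave 37 of 90 against 32.1 (adjusted permutation p = 0.361), and 53 of 123 against 44.0 with mesoderm and junction genes added (adjusted permutation p = 0.135). Lists of other cell types combined gave 21 of 88 against 27.5 (adjusted permutation p = 0.192). Set against each other without length matching, the muscle and the other cell type lists differed (odds ratio 2.23, 2-sided Fisher's exact test, p = 0.0166).

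In a scan of all 2080 hexamers, reverse complements merged, 369 were more frequent at summits than in flanks and 627 less frequent after adjustment. TAAATA, part of the Fox word, ranked 1 by p, at 41.7% of summits against 28.6% of flanks. ACAGTG was present at 15.5% against 7.39%, a ratio of 2.10, and at 6.68% of GC-matched windows. ACACTG was present at 14.8% against 7.40%. Both exceeded CAGCTG in their ratio to flanks, and CAGCTG ranked 12, but against GC-matched windows the ratio was 2.41 for CAGCTG, 2.32 for ACAGTG and 2.03 for ACACTG. CCAGGA was the most depleted by p, at 1.75% against 7.40%, and at 6.49% of GC-matched windows. The scan used all flanks, of which 14.5% lay in coding exons. The GC-matched windows were not filtered for coding exons either, which held 13.3% of random placements and 0.212% of IDR summits. Depletion such as that of CCAGGA was thus not separated from the scarcity of summits in coding exons. Regions ranked just below the IDR list, as many as it holds, had CAGCTG in 13.9% of cases against 8.30% of their flanks, a ratio of 1.67.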
